A study of Glycine max with 6 samples.

How the data were processed

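RNA was measured on 6 soybean arrays of the Affymetrix Soybean GeneChip, a 3' expression array on which a probe set reports 1 transcript or a few related ones. Per the labels, the 6 arrays fall into 3 groups of 2: the microdissected shoot apical meristem, the vegetative axillary meristem, and a pool of stem, root and mature leaf that is called non-meristem tissue here. The labels describe the 2 arrays of each group as independent biological replicates, without saying how the plants were divided between them. The label protocol gives 3 µg of total RNA for the shoot apical and non-meristem samples. An age of 10 days is given for both axillary samples and for 1 of the non-meristem samples.

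The deposited values are log2 signals per probe set, made with RMA per the submitters' processing notes. The version of RMA, and whether all 6 arrays were processed together, are not given in the sources used here. The values ran from 2.35 to 14.4 with no missing value, and were used without further normalization. Of 37776 rows, 135 control probe sets were left out, and 37641 soybean probe sets were tested, among them 48 for ribosomal RNA. Arrays carry no read depth, so their number limits the precision.

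Gene names came from the platform annotation, which lists 9047 of the probe sets. Of these, 8677 have 1 gene and 370 have several, and the remaining 28729 are unnamed here. Symbols were updated through the Entrez ID with RefSeq's gene table for Glycine_max_v4.0, in which 8652 of the probe sets found a match. That table was used for names only. Where a gene had several probe sets, the one with the highest mean over the 6 arrays was used, which left 6031 genes. For 1131 of them the tables give a symbol or synonym beyond a locus number, and only these are named.

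Differences between group means were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes over all 6 arrays in 1 model of 3 group means and 3 residual degrees of freedom. All tests were two-sided. Values of p were adjusted by Benjamini-Hochberg over the 37641 probe sets of a contrast, and an adjusted p under 0.05 counted as a call. Unless said otherwise, an adjusted p is limma's, a ± after a log2 difference is its standard error from that model, and each group mean rests on 2 arrays. The model assumes 1 spread for all groups, while the pooled SD was 0.175 for the shoot apical, 0.24 for the axillary and 0.64 for the non-meristem arrays. For a difference from non-meristem tissue the ± and the p can therefore be too small, above all where the 2 non-meristem arrays lie apart. Between the meristems they can be too large.

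A probe set was taken as not above background on an array when it lay under the 95th percentile of 33 control probe sets without a soybean target. Where every array of the dimmer group was under that level, the fold is given as a bound ("at least"), from the mean of the bright group against the mean background level of the dim group's arrays. After the data were seen, the bound was also used where only the mean of the dimmer group lay under its mean background level. Where the bound came to 1 or both groups were below background, no fold is given.

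There were 20 gene lists fixed before the data were examined, as search patterns for symbols and product descriptions. The tables used here carry no product descriptions, so the lists were completed with gene symbols after the annotation was seen but before any soybean gene's values were. A list with at least 5 genes was tested with limma's camera against the other genes, with a preset inter-gene correlation of 0.01. Its p was adjusted over the 16 lists tested and the 3 contrasts. Each list test was repeated with an estimated correlation. Members were also counted with p adjusted over the list alone.

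The genes named were chosen by a rule set beforehand. It takes the 8 largest rises and the 8 largest falls in each comparison with non-meristem tissue, and the 5 largest each way between the meristems. These had to pass the threshold with no overlap between the arrays of the groups compared. The rule adds up to 2 members in each direction per list and contrast, and a few genes of prior interest, whatever their result. Genes named outside the rule are marked as such or are members of a list whose count they explain.

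The steps were tested on simulated data with the groups' unequal spreads. Each probe set had its spread as limma estimated it, which is drawn towards a common value. With 200 changed probe sets among 37641, 48% of 4-fold changes and 1.6% of 2-fold changes were recovered for the shoot apical meristem against non-meristem tissue. The axillary comparison gave 48.3% and 1.9%. Between the meristems 48.6% of 4-fold changes were recovered and 0% of 2-fold changes. With 12000 changed probe sets, 9.65% of the calls were false for the shoot apical comparison and 10.5% for the axillary one, above the nominal 5%. In 50 simulated lists of 20 genes, camera found 100% of those shifted by a log2 of 1 and 4% of the unshifted ones. The simulated genes varied independently, so this does not test camera on lists whose genes vary together.

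Alternatives set before the data were examined were other scalings, a limma variance trend, only the compared groups in the model, a replicate block, leaving out each array, leaving out probe sets that match several transcripts, a 2-fold minimum, the mean over a gene's probe sets, and an estimated correlation for lists. After the data were seen, 6 more were added, which concern the labelling controls, unequal spread, background and ribosomal RNA. Probe sets for soybean pathogens, planned as a background measurement, are not analysed here, so all soybean probe sets were tested.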

Results

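Transcript levels were compared between 2 kinds of soybean meristem and the differentiated organs of the plant. Meristems are the small groups of dividing cells from which shoots form their organs. The shoot apical meristem (SAM) sits at the tip of the shoot, and axillary meristems (AM) sit where leaves join the stem. Non-meristem tissue (NM) was a pool of primary stem, primary root and mature leaf. There were 2 arrays per tissue. Between 67.6% and 73.9% of the probe sets lay above background on an array.

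The arrays of the meristems resembled one another closely. Across probe sets, which are not independent replicates, Pearson's r was 0.9948 between the SAM arrays and 0.9897 between the AM arrays. Between a SAM and an AM array it lay between 0.9843 and 0.9936, and between a meristem and an NM array between 0.7921 and 0.8467. The 2 NM arrays were farther apart than the arrays of either meristem, with r of 0.9245 and 6212 probe sets (16.5%) at least 2-fold apart. The AM arrays had 775 such probe sets and the SAM arrays 177. The first principal component, with 80.4% of the variance, set both meristems against NM, and the second, with 13.8%, parted the NM arrays.

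Control probe sets differed between arrays, also within a tissue. The 4 labelling controls, bacterial transcripts added to the sample, had a mean log2 signal of 8.46 and 9.13 on the SAM arrays. They had 4.81 and 8.0 on AM replicates 1 and 2, and 4.0 and 6.54 on NM replicates 1 and 2. The 18S ribosomal RNA control followed them, with 11.6 and 12.1 for SAM, 9.19 and 11.7 for AM, and 7.40 and 10.3 for NM. The actin control was brighter at its 3' than at its 5' end by 1.89 and 1.98 for SAM, 1.22 and 1.89 for AM, and 0.61 and 0.91 for NM. Differences are therefore also given between AM and NM replicate 1, which both had low labelling controls, and between their replicates 2.

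**Figure D1:**
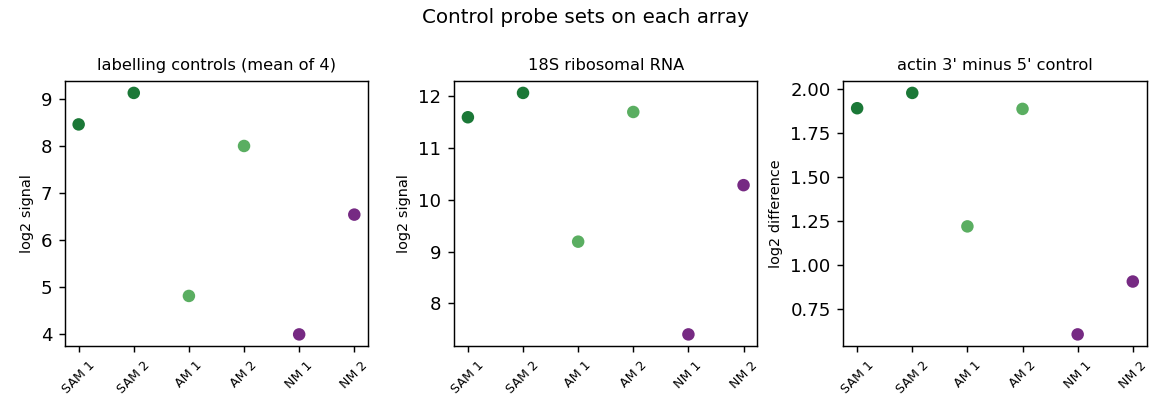
Log2 signal of the labelling controls (mean of 4 probe sets), log2 signal of 18S ribosomal RNA, and the log2 difference between the 3' and 5' actin controls, 1 point per array. The lowest labelling and 18S values are those of AM replicate 1 and NM replicate 1 (4.81 and 4.0 for the labelling controls).

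The first comparison asked which transcripts distinguish the SAM from differentiated tissue. The SAM carried far more transcript of the knotted-like homeobox gene H1 (also called Sbh1), a KNOX gene of the class that keeps meristem cells undifferentiated, at least 19.1-fold above NM. Genes of DNA replication rose with it. Of 18 photosynthesis genes 13 fell (camera adjusted p = 0.000567; 14 adjusted over the list alone), and of 32 cell wall, lignin and vascular genes 20 fell (camera adjusted p = 0.000929; 20 adjusted over the list alone). Neither list passed with an estimated correlation (adjusted p = 0.339 and adjusted p = 0.493). The largest rise of a named gene was that of SACPD-C, a stearoyl-acyl carrier protein desaturase that makes oleic from stearic acid, at least 79.5-fold (adjusted p = 0.000506), and SHOOT2 rose by 5.24 ± 0.30 on the log2 scale. In all, 13913 of 37641 probe sets (37%) passed the test, 7569 higher and 6344 lower in the SAM, and 10979 of them differed at least 2-fold.

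Among the other leading rises in the SAM, SHOOT2 was 37.9-fold higher and the glutathione transferase GSTF7 higher by at least 4.49 on the log2 scale. IQD18, of a calmodulin-binding family, was 19.0-fold higher, and the lipoxygenase LOX10 was 18.2-fold higher. FCL2 was at least 12.4-fold higher and the transcription factor WRKY15 at least 11.6-fold higher. The largest fall was that of LOC100816355 (GmCUPIN16.1), a cupin, at 323-fold lower (log2 difference -8.34 ± 0.22). The germin-like GER10 was 125-fold lower and LOC732565 (SGT3) 98.4-fold lower. For 5 further leading falls the meristem was below background, so that only bounds exist. These were CYP83E8, a cytochrome P450, at least 65.3-fold lower, SEOA at least 61-fold, VPE2, a vacuolar processing enzyme, at least 38.4-fold, SLR1 at least 37.4-fold, and AS2 at least 21.9-fold. Adjusted p of these leading genes ran from 0.000152 for SEOA to 0.00347 for VPE2. The probe sets of SLR1 did not all go 1 way, as 4 of its 5 others had the same sign.

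In the list of KNOX and stem-cell regulators, with 3 genes too small for a list test, H1 rose at least 19.1-fold (adjusted p = 2e-04). CLV1A and NARK, receptor kinases of the CLAVATA1 type, passed the test in the other direction. CLV1A was at least 1.62-fold lower. NARK was not above background in either tissue and is given no fold. Of 6 genes for organ boundaries and polarity, 2 rose and 1 fell (camera adjusted p = 0.815; 2 and 1 adjusted over the list alone). PHANa, a MYB gene of the PHANTASTICA type that represses KNOX genes in leaf primordia, rose by 3.22 ± 0.53 (adjusted p = 0.00785), with NM arrays at 8.11 and 9.75. PHANb, in the same list, was at 0.60 ± 0.39 and did not pass (adjusted p = 0.283), with NM arrays at 7.25 and 8.41. Of 3 YABBY genes, LOC100500026 (GmYABBY9) was 1.92-fold higher, LOC100785458 (GmYABBY12) was 3.07-fold lower, and LOC100500091 (GmYABBY11), at -0.67 ± 0.34, did not pass (adjusted p = 0.184).

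All 5 genes of the list for the cell cycle and DNA replication rose in the SAM, with a median log2 difference of 2.49 (camera adjusted p = 0.00397; 5 adjusted over the list alone). With an estimated correlation the list did not pass, at adjusted p = 0.339. CCS52, an activator of the anaphase-promoting complex known for its part in endoreduplication, rose 10.3-fold. LOC548079 (PCNA), the sliding clamp of DNA polymerase, rose 6.38-fold. POLD1, a DNA polymerase delta subunit, and LOC100808044 (FEN-1), a flap endonuclease, also rose, POLD1 by 2.49 on the log2 scale. The fifth member was CDC48, a chaperone with roles beyond division. The median of the list was 2.15 against NM replicate 1 and 2.64 against NM replicate 2.

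In the list of histones and chromatin 6 of 7 genes rose, with a median of 1.65, and 1 fell (camera adjusted p = 0.0506, and adjusted p = 0.848 with an estimated correlation; 6 and 1 adjusted over the list alone). None of the 6 is a histone. They include the histone deacetylase HD2A, 5.52-fold higher, FVE, 4.72-fold higher, and SNF5, a chromatin remodelling subunit, higher by 2.22 on the log2 scale. The gene that fell was H4, a core histone, at least 11-fold lower in the SAM in its brightest probe set (adjusted p = 0.00144). That probe set is of a type that can match several transcripts, and its identifier shares a stem with that of VSPA. The fall may therefore not be that of H4, although its 1 other probe set had the same sign. All 5 ribosomal protein genes rose, with a median of 0.74 (5 adjusted over the list alone), and as a list they did not pass, at camera adjusted p = 0.055. RPL2 was 1.99-fold and RPS13 1.73-fold higher. Of the 48 ribosomal RNA probe sets, 15 were called higher, and these followed the labelling controls on the arrays.

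Photosynthesis genes were lower in the SAM. Of 18 genes, 13 fell and 1 rose, with a median of -2.16 (camera adjusted p = 0.000567; 14 and 1 adjusted over the list alone), and adjusted p = 0.339 with an estimated correlation. FBP, the fructose-bisphosphatase of the Calvin cycle, was 16.7-fold lower, and ATPC, a subunit of the chloroplast ATP synthase, 16.1-fold lower. The light-harvesting gene LOC547819 (LHCP) was lower, at -2.67 ± 0.61 (adjusted p = 0.0217), with NM arrays at 14.04 and 12.14. CAB3, a chlorophyll-binding protein gene, had a log2 difference of -1.14 ± 0.38 and did not pass (adjusted p = 0.068). The member that rose was RCABETA, a rubisco activase, at 1.55-fold. The list's median was -2.01 against NM replicate 1 and -1.89 against NM replicate 2.

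Genes of the cell wall, lignin and vascular tissue were also lower, with 20 of 32 falling and 5 rising and a median of -2.01 (camera adjusted p = 0.000929; 20 and 6 adjusted over the list alone). This list too did not pass with an estimated correlation, at adjusted p = 0.493. Among the largest falls were genes of sieve element occlusion proteins, which plug wounded phloem: SEOA at least 61-fold and SEOF at least 41.1-fold. Of the 5 that rose, 4CL, an enzyme at the entry to lignin and flavonoid synthesis, was 6.21-fold higher, and PGIP, an inhibitor of pectin-degrading enzymes, 4.23-fold higher. The gene 4CL1, looked up outside the rule, passed in the other direction, at least 11.7-fold lower. PAL2.1, phenylalanine ammonia-lyase, was higher by 1.26 in its brightest probe set but lower in its other probe sets. The median against NM replicate 1 was -1.86 and against NM replicate 2 -1.89.

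Of 21 gibberellin genes, 9 fell and 2 rose, with a median of -1.18 (camera adjusted p = 0.193; 9 and 3 adjusted over the list alone). All 9 that fell belong to the GASA family of small gibberellin-regulated peptides, led by GASA22 at least 60.5-fold and GASA11 at 43.5-fold lower. GA2OX8, a gibberellin 2-oxidase that inactivates the hormone, was 13.0-fold higher, and GASA21 was 7.95-fold higher. Of 9 auxin genes 2 rose and 4 fell (camera adjusted p = 0.555; 2 and 4 adjusted over the list alone). LAX11, an auxin influx carrier, was 5.63-fold higher and the receptor AFB3B 2.65-fold higher. ADR11 was 7.92-fold lower and AUX22, an Aux/IAA repressor, 7.80-fold lower. Of 10 ethylene genes the receptor ETR2 alone passed, 2.79-fold higher (camera adjusted p = 0.913; 1 and 0 adjusted over the list alone). The 3 cytokinin genes lay at background on all arrays.

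Of 19 genes of jasmonate and lipoxygenases, 3 rose and 4 fell (camera adjusted p = 0.916; 3 and 4 adjusted over the list alone). Beside LOX10, LOX9 was 2.91-fold higher, while the allene oxide cyclase AOC6 was 6.61-fold lower and the lipoxygenase VLXC 6.08-fold lower. Among 34 genes of abscisic acid, dormancy and late embryogenesis, 20 lay at background on all arrays. Counted over all 34, 3 rose and 4 fell (camera adjusted p = 0.629; 1 and 3 adjusted over the list alone). The rise of PGMPM10 and the fall of PM34 lie between signals at background on all arrays, so neither is given a fold. ZEP, the zeaxanthin epoxidase, was lower, at -3.47 ± 0.59, with NM arrays at 10.9 and 9.11. Of 25 flowering and MADS-box genes 2 rose and 4 fell (camera adjusted p = 0.565; 1 and 4 adjusted over the list alone), and 8 of the 25 lay at background on all arrays. AG1, placed in this list by its name only, was lower, at -4.69 ± 0.73 with SAM arrays at 7.65 and 5.39. LOC100793296 (COL19) was at least 6.91-fold lower. FT1A lay at background in all 3 tissues.

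Of 36 genes of phenylpropanoid, flavonoid and isoflavone synthesis, 5 rose and 13 fell (camera adjusted p = 0.304; 5 and 14 adjusted over the list alone), and 9 of the 36 lay at background on all arrays. The chalcone reductases CHR1 and CHR5 were 6.26-fold and at least 3.54-fold higher, and the chalcone synthase CHS1 was 25.1-fold lower. Of CHS1's 6 other probe sets 5 had the same sign. Of 49 root and nodule genes, 17 lay at background on all arrays. Counted over all 49, 17 fell and 4 rose (camera adjusted p = 0.109; 18 and 5 adjusted over the list alone). The rise of PHT1-8 lies between signals below background in both tissues and is given no fold. Of those that fell, 9 are plasma membrane aquaporins, which are not confined to roots. PIP2-8 was lower by 4.58 on the log2 scale and the tonoplast aquaporin LOC100306092 (TIP2-3) was 16.2-fold lower. Of 32 defence and storage proteins 4 rose and 5 fell (camera adjusted p = 0.925; 4 and 5 adjusted over the list alone), while 21 of the 32 lay at background on all arrays. The Bowman-Birk protease inhibitor BBI-1 was at least 10.1-fold higher. The vegetative storage protein gene VSPA was 2.26-fold lower, and LOC547820 (VSPB) was lower, at -2.46 ± 0.58, with SAM arrays at 11.9 and 10.0.

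Of 75 genes for heat shock and handling stress 19 rose and 6 fell (17 and 6 adjusted over the list alone), and 12 of the 75 lay at background on all arrays. The list's median was -0.07 while its mean was 0.12 and camera ranked it upwards, without passing (adjusted p = 0.555). WRKY transcription factors make up 52 of the 75 genes. Of these 8 rose, led by WRKY15, 4 fell and 40 did not pass, with a median of -0.25. As a family they did not pass (camera adjusted p = 0.952 over the families counted below). The list's median thus rests largely on WRKY genes. Another 5 of the 19 are heat shock factors. HSP17.5-E, a small heat shock protein, was 7.32-fold higher, and DREB1 at least 6.5-fold and WIN 13.7-fold lower. The list's median was -0.13 against NM replicate 1 and 0.29 against NM replicate 2. The 1 gene for epidermis and cuticle, HPS, lay at background on all arrays. The list for small RNA pathways held no gene.

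**Figure D2:**
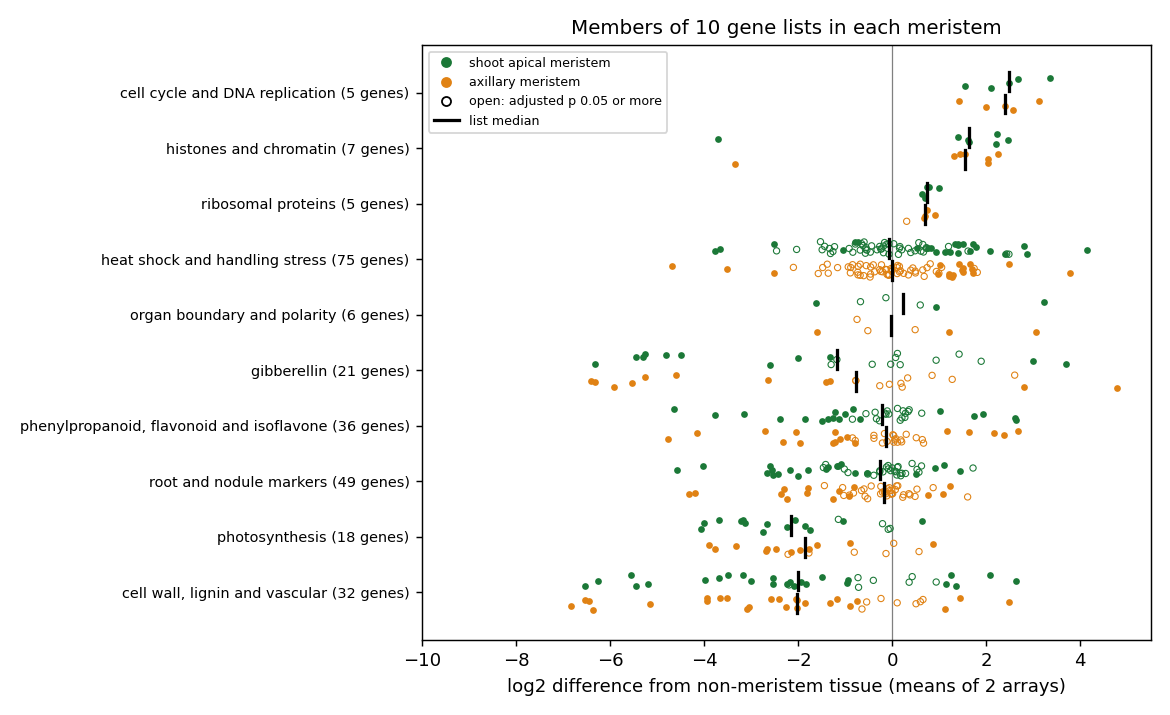
Log2 difference of each member of 10 gene lists between the SAM (green) or the AM (orange) and NM, each from means of 2 arrays; filled points passed an adjusted p of 0.05, open ones did not, and black bars are list medians. Cell cycle genes lie to the right of 0 in both meristems (medians 2.49 and 2.41), and photosynthesis and cell wall genes mostly to the left.

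The count of calls depended on single arrays. Leaving out a SAM array gave 5107 calls without replicate 1 and 4852 without replicate 2, while leaving out NM replicate 2 gave 22085, with the lone array assumed to vary like the other groups. The measured fold of GER10, LOC732565 (SGT3), VPE2, AS2, PHANa, LOC547819 (LHCP), GASA11, ZEP, AG1, LOC100793296 (COL19), BBI-1, LOC547820 (VSPB), DREB1 and WIN also moved by over 1.5 times when 1 array was left out. The called probe sets, chosen on these same arrays, had a median difference in the called direction of 1.59 against NM replicate 1 and 1.37 against NM replicate 2.

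The second comparison set the AM against the same NM arrays. SACPD-C was again the largest rise of a named gene, at least 33.1-fold, and H1 was at least 21-fold higher. GA2OX8 was among the 8 largest rises here, at 27.5-fold (log2 difference 4.78 ± 0.18), and SHOOT2 was not. Of 18 photosynthesis genes 12 fell (camera adjusted p = 0.00154; 12 adjusted over the list alone), and of 32 cell wall, lignin and vascular genes 22 fell (camera adjusted p = 0.000481; 22 adjusted over the list alone). Neither list passed with an estimated correlation (adjusted p = 0.339 and adjusted p = 0.464). In all, 12871 probe sets passed (34.2%), 7242 higher and 5629 lower in the AM, and 10036 differed at least 2-fold. The count was 4824 without AM replicate 1, 5161 without AM replicate 2 and 21540 without NM replicate 2, and 7536 without either SAM array or with only AM and NM in the model. The called probe sets, chosen on these same arrays, had a median difference in the called direction of 1.54 between the replicates 1 and 1.34 between the replicates 2. The measured fold of VPE2, AS2, PHANa, LOC547819 (LHCP), GASA27, BBI-1 and WIN moved by over 1.5 times when 1 array was left out.

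The other leading rises in the AM were those of LOX10 (20.7-fold), GSTF7 (at least 17.8-fold), IQD18 (16.4-fold), FCL2 (at least 12.4-fold) and WRKY15 (at least 8.90-fold). The leading falls were LOC100816355 (GmCUPIN16.1) at least 326-fold, GER10 at least 161-fold, and PRP3, a proline-rich cell wall protein, at 114-fold. CYP83E8 was at least 62.6-fold lower, SEOA at least 58.4-fold, VPE2 at least 36.8-fold, SLR1 at least 35.8-fold and AS2 at least 21-fold. Their adjusted p ran from 0.000167 for SEOA to 0.00374 for VPE2.

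All 5 cell cycle and DNA replication genes rose in the AM, with a median of 2.41 (camera adjusted p = 0.00397; 5 adjusted over the list alone; adjusted p = 0.339 with an estimated correlation). The median was 2.04 between the replicates 1 and 2.59 between the replicates 2. LOC548079 (PCNA) was 5.93-fold and CCS52 8.78-fold higher. In the list of histones and chromatin 6 of 7 rose and H4 fell 10.1-fold (camera adjusted p = 0.0506; 6 and 1 adjusted over the list alone). The H4 value is from the same probe set, with the same doubt. HD2A was 4.79-fold and FVE 4.12-fold higher. Of 5 ribosomal protein genes 4 rose (camera adjusted p = 0.0758; 4 adjusted over the list alone), RPL2 1.89-fold. Of the ribosomal RNA probe sets 7 were called higher.

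Of 18 photosynthesis genes 12 fell and 1 rose in the AM, with a median of -1.86 (camera adjusted p = 0.00154; 12 and 1 adjusted over the list alone; adjusted p = 0.339 with an estimated correlation). The median was -1.96 between the replicates 1 and -1.53 between the replicates 2. FBP was 14.8-fold and ATPC 13.6-fold lower, LOC547819 (LHCP) was at -2.47 ± 0.61, and RCABETA was 1.82-fold higher. CAB3 had a log2 difference of -0.80 ± 0.38 and did not pass (adjusted p = 0.167). Of 32 cell wall, lignin and vascular genes 22 fell and 3 rose, with a median of -2.03 (camera adjusted p = 0.000481; 22 and 4 adjusted over the list alone; adjusted p = 0.464 with an estimated correlation). The median was -1.87 between the replicates 1 and -1.85 between the replicates 2. The 3 that rose were 4CL, 5.63-fold higher, PAL2.1 and XTH1. Here too 4CL1, looked up outside the rule, passed in the other direction, at least 11.2-fold lower. PAL2.1 was 2.72-fold higher in its brightest probe set and lower in its 2 others.

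In the remaining lists none passed camera's test in the AM. Of 21 gibberellin genes 9 fell and 2 rose (adjusted p = 0.229; 9 and 2 adjusted over the list alone), with GASA27 80.2-fold and GASA22 at least 57.9-fold lower. Of 9 auxin genes 2 rose and 4 fell (adjusted p = 0.555; 2 and 4 adjusted over the list alone), with LAX11 5.94-fold higher and AUX28 at least 2.24-fold lower. No ethylene gene passed (adjusted p = 0.676). Jasmonate and lipoxygenase genes gave 3 rises and 3 falls of 19 (adjusted p = 0.723; 3 and 3 adjusted over the list alone), among them VLXB, 4.06-fold lower. Of the 34 genes of abscisic acid, dormancy and late embryogenesis 5 fell (adjusted p = 0.37; 1 adjusted over the list alone), with LEA-2 5.11-fold lower. PM34, also among those that fell, lay at background on all arrays and is given no fold.

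Flowering and MADS-box genes gave 1 rise and 4 falls of 25 in the AM (camera adjusted p = 0.629; 1 and 4 adjusted over the list alone), with AG1 48.5-fold lower. Flavonoid genes gave 5 rises and 12 falls of 36 (adjusted p = 0.304; 5 and 13 adjusted over the list alone). The isoflavone malonyltransferase IF7MaT was 5.18-fold higher and the chalcone isomerase CHI2-A 17.8-fold lower. Root and nodule genes gave 3 rises and 11 falls of 49 (adjusted p = 0.175; 3 and 11 adjusted over the list alone), with PIP2-8 18.2-fold lower. The rise of PHT1-8 again lies between signals below background in both tissues. Defence and storage protein genes gave 4 rises and 5 falls of 32 (adjusted p = 0.882; 4 and 4 adjusted over the list alone), with BBI-1 at least 9.18-fold higher and LOC547820 (VSPB) 5.86-fold lower. Heat shock and handling stress genes gave 15 rises and 3 falls of 75 (adjusted p = 0.492; 15 and 3 adjusted over the list alone). HSP17.5-E was 5.59-fold higher, and WIN at least 20.5-fold lower. That list's median was -0.08 between the replicates 1 and 0.34 between the replicates 2. For boundary and polarity genes, 2 rose and 1 fell of 6 (adjusted p = 0.913; 2 and 2 adjusted over the list alone), with PHANa at 3.07 ± 0.53. PHANb, at 0.49 ± 0.39, did not pass (limma adjusted p = 0.385).

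**Figure D3:**
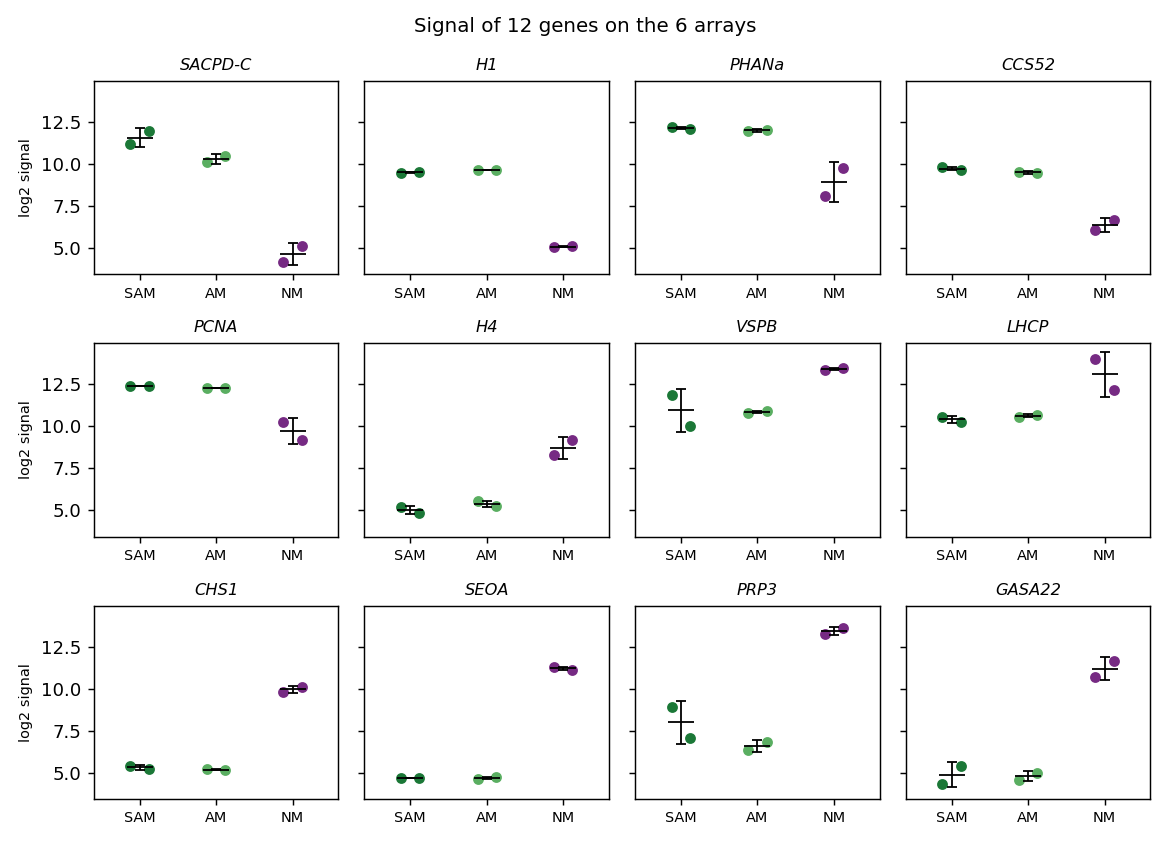
Log2 signal of 12 genes on each array (points) with the mean and SD of the 2 arrays of a tissue (bars). H1 lies at 9.51 in the SAM, 9.64 in the AM and 5.08 in NM, and SEOA at 4.68, 4.68 and 11.2.

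The calls of the 2 comparisons overlapped. Of the probe sets called in both, 6609 were higher and 5399 lower in both meristems, 12008 in all, and 1 was called in opposite directions. The overlap of SAM vs NM and AM vs NM calls ran from 4763 without SAM replicate 2 to 20268 without NM replicate 2, and was 7336 with only the compared groups in the model. In 100 simulations no group differed from another, and both comparisons shared the 2 simulated NM arrays. On average 0.11 probe sets were called in both with the same sign. With nothing changed, almost no probe set is called. That count therefore cannot tell whether 2 meristems that each differ from NM share their changes. Independent lists of these sizes would share 1456 higher and 949 lower probe sets. The log2 differences of the 2 comparisons had r of 0.9774 across probe sets against 0.901 in the simulation, and a covariance of 1.73 against 0.141. With 1 NM array for each comparison, the covariance was 1.52 and 1.54 and r 0.7717 and 0.7845 for the 2 ways of dividing them. Calls were not counted on divided controls, where NM would have no spread of its own, so part of the excess may come from the shared controls.

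The third comparison asked what sets the 2 meristems apart. No probe set passed the limma test between the SAM and the AM, with 915 at an unadjusted p under 0.05 where 1882 would be expected by chance. With the 4 meristem arrays alone in the model, 3294 lay under that value and the smallest adjusted p was 0.177, again with 0 calls. H1 differed by -0.13 ± 0.15 on the log2 scale, SAM minus AM, and LOC548079 (PCNA) by 0.11 ± 0.36. Of all probe sets, 95% differed by less than 0.59.

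At least 2-fold apart between the meristem means were 451 probe sets, 205 higher in the SAM and 246 higher in the AM. AM replicate 2 lay closer to the SAM arrays (r of 0.9936 and 0.9916) than to AM replicate 1 (r of 0.9897). The differences may thus rest in part on AM replicate 1, which had low labelling controls. In 401 of the 451 the arrays of the meristems did not overlap, which choosing by a 2-fold difference of means favours. Over all probe sets 41% had no such overlap, where chance gives 33.3% for 2 arrays against 2. Among the named genes with the largest differences, chosen after their values were seen, SHOOT2 was at 11.1 and 11.8 on the SAM arrays and at 9.26 and 9.69 on the AM arrays. NOD33, from the list of root and nodule genes, was at 8.89 and 9.38 in the SAM and at 10.7 and 11.1 in the AM. MYB184 was above background on both AM arrays, at 5.97 and 5.77, and below it on both SAM arrays. None of these passed the adjustment, with an adjusted p of 1.

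List tests found 2 lists lower in the SAM than in the AM. No member of either was called over all probe sets, and adjusted over the list alone 0 photosynthesis genes and 1 root and nodule gene passed. The photosynthesis list had a median of -0.24 (camera adjusted p = 0.000567), and adjusted p = 0.339 with an estimated correlation. With the labelling state of the arrays as a term its median was -0.16 and it did not pass. The root and nodule list had a median of -0.11 (camera adjusted p = 0.0308), and adjusted p = 0.339 with an estimated correlation. It did not pass with the labelling state as a term (median -0.08), without SAM replicate 1 (median -0.08) or without AM replicate 1 (median -0.11). AM replicate 1 had low labelling controls and both SAM arrays had high ones. The smallest adjusted p of the other 14 lists was 0.116, for the cell wall list.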

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

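The tests of labelling state on the spread of the NM arrays, on pairs of arrays with opposite controls and as a term, and the choice of probe sets in the test of 3' bias, were set up after the results were seen. Control and ribosomal RNA probe sets differed between meristem and non-meristem arrays. The mean of the 4 labelling controls was 7.60 on the meristem arrays and 5.27 on the NM arrays, a difference of 2.33. The median of the ribosomal RNA probe sets in the sense orientation, which are part of the 48 tested, differed by 2.28 and the actin 3' minus 5' control by 0.99 in the same direction.

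The first pattern is the large share of probe sets that separates meristems from NM. AM replicate 1 had lower labelling controls than NM replicate 2, and AM replicate 2 higher ones than NM replicate 1, so labelling state as the cause would turn the direction between these 2 pairs, which share no array. Of 14769 probe sets at least 2-fold apart in the latter pair, 88.7% had the same direction in the former. This argues against labelling state as the whole cause for the AM. With labelling state as a term, 12960 of 37641 probe sets were called for the SAM and 14948 for the AM. That term set only the replicates 1 of AM and NM apart as low. It left NM replicate 2 (6.54) with AM replicate 2 (8.0) and the SAM arrays (8.46 and 9.13), so these counts decide nothing. The ratio of 1.15 between the medians for the replicates 1 and the replicates 2 (1.54 and 1.34) decides nothing either, since a call needs like arrays within a group. Stronger 3' bias as the cause would put AM replicate 1, whose actin control lay nearer to NM, nearer to NM in the called probe sets too, but its shift was 0.98 of that of AM replicate 2 in the 10070 probe sets called with the SAM and NM arrays alone, which argues against it. A difference between the tissues remains as a hypothesis, and single probe sets, those of ribosomal RNA above all, may still follow the controls.

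The second pattern is the distance between the 2 NM arrays. If the pools held different shares of leaf and root, photosynthesis genes should move against root and nodule genes. Their medians in replicate 2 minus replicate 1 were -0.24 and 0.04, a difference larger than in 78.4% of 10000 random pairs of lists, which decides neither way. If labelling state were the cause, the AM arrays should differ in the same direction. They did so in 60.3% of the 6212 probe sets concerned, with a median of 0.07 against 1.37 between the NM arrays, so that labelling state may account for a small part at most but cannot be told apart by the bounds set. A difference between the plants pooled stays open and was not tested.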

How the results depend on the processing

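The alternatives that concern labelling controls, weights, background controls and ribosomal RNA were chosen after the data were seen. The SAM against AM count was 0 under all alternatives. Counts moved by over 1.5 times only with AM and NM alone in the model (7536 calls for AM vs NM, and 7336 for the overlap of SAM vs NM and AM vs NM calls) and when arrays were left out. Leaving out 1 array gave 4852 to 22085 calls for SAM against NM, 4824 to 21540 for AM against NM and an overlap of SAM vs NM and AM vs NM calls of 4763 to 20268. Fewer arrays of a group with small spread lower the count, and leaving out an NM array removes the largest spread from the model. Without the 2 arrays with low labelling controls the counts were 18216 and 14903, and with array weights per group 10509 and 8905. Replicate numbers shared no deviation that would pair the arrays (r of -0.19, 0.15 and -0.05 between groups), and a replicate block gave 12711 and 11483 calls. No called list kept its call with an estimated correlation, where the medians were the same by construction: 2.49, -2.16 and -2.01 for cell cycle, photosynthesis and cell wall genes in the SAM, 2.41, -1.86 and -2.03 in the AM, and -0.24 and -0.11 for photosynthesis and root genes between the meristems. The histone and chromatin list passed with median centring (1.51 for the AM), with the replicate block or array weights (1.65 and 1.56 each), with labelling state as a term (1.51 and 1.56) and with centring on background controls (1.55 and 1.48); with 1 array left out its median ran from 1.505 to 2.13 for the SAM and from 1.35 to 1.95 for the AM. Ribosomal protein genes passed in the SAM with the mean over probe sets (0.80), and root genes with a filter on background controls (-1.15). Heat shock genes passed in the AM without the low-control arrays (0.34), and with 1 array left out ranged from -0.13 to 0.29 in the SAM and from -0.10 to 0.31 in the AM. Between the meristems, labelling state as a term gave -0.16 for photosynthesis, -0.0792 for root genes, 0.12 for abscisic acid genes and 0.12 for heat shock genes, the last 2 now past the threshold. Root genes gave -0.11 without the low-control arrays, and jasmonate genes passed with array weights (-0.18). With 1 array left out, the medians were -0.11 to -0.0364 (list shift: root and nodule markers, SAM vs AM), -0.0347 to 0.13 (list shift: cell wall, lignin and vascular, SAM vs AM) and 0.0206 to 0.0576 (list shift: abscisic acid, dormancy and LEA, SAM vs AM). They were -0.28 to -0.0091 for jasmonate and lipoxygenase, SAM vs AM, and -0.33 to 0.0184 for abscisic acid, dormancy and LEA, AM vs NM. PAL2.1 reversed with the mean over its probe sets, to -1.18 in the SAM and -0.96 in the AM, since its probe sets disagree. For the other changes the cause was not tested. For named genes under alternatives, 1141 values kept side and direction in SAM against NM, 103 no longer passed and 3 newly passed. In AM against NM these were 1130, 97 and 20, and between the meristems no value passed under any setting. A stricter filter and centring on pathogen probe sets were not run, and a pseudocount does not apply to log2 values. Genes near background, such as NARK and CLV1A, have differences that the background limits.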

Other observations

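Gene families that share a symbol were counted after the data were seen. Of 58 bZIP genes 16 rose and 13 fell in the SAM, with BZIP130 at least 7.32-fold higher. Of 66 MYB genes 7 rose and 13 fell. Neither family passed (camera adjusted p = 0.933 for bZIP and 0.341 for MYB genes over these families). For comparison, 190 of all 1131 named genes rose in the SAM and 293 fell. Of 22 glutathione transferases 10 fell in each meristem and GSTF7 alone rose (camera adjusted p = 0.0785 in the SAM and 0.0911 in the AM over these families). The falls included GSTU28 at -3.01 ± 0.22 in the SAM.

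Of 8 sieve element occlusion genes 7 fell in each meristem, with medians of -3.74 in the SAM and -3.80 in the AM (camera adjusted p = 0.00111 and 0.000698; adjusted p = 0.638 with an estimated correlation). These genes are part of the cell wall and vascular list, so this is no independent result. Of 8 SWEET sugar transporter genes 3 fell and none rose in either meristem (family adjusted p = 0.235 in the SAM and 0.224 in the AM). Of 14 plasma membrane aquaporins 9 fell in the SAM and PIP2-1 alone rose (adjusted p = 0.0436, and 0.638 with an estimated correlation), while in the AM 7 fell and the family did not pass (adjusted p = 0.0785). Of 10 heat shock factors 5 rose and none fell in the SAM, and 3 rose in the AM, while the family did not pass (adjusted p = 0.153 and 0.235).

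The last pattern weighed is the absence of calls between the SAM and the AM. The wide spread of the NM arrays, which enters the shared variance, is a possible explanation, as the median standard error fell from 0.235 to 0.126 when the NM arrays were left out. The 4 meristem arrays alone gave 0 calls at that smaller error, so taking out the spread of NM did not by itself bring calls. That model also has fewer residual degrees of freedom, which lowers its power. Unadjusted p under 0.05 rose from 915 to 3294 probe sets in it, so how much the spread of NM hides is not decided. A fit with array weights, also with 0 calls, had been seen before this test. In simulated data with the meristems' own spread as limma estimated it, 100 of 37641 probe sets changed 2-fold and 100 changed 4-fold. The model of the 4 meristem arrays recovered 69.7% of the former and 98.4% of the latter, with 14.9 false calls on average. Those spreads were already drawn towards a common value, so recovery in the measured data may be lower. None of the 451 measured probe sets at least 2-fold apart between the meristem means was called. Differences of 2-fold, smaller ones or few ones therefore stay open. With labelling state as a term 0 probe sets were called, but that model kept the NM spread. The difference in labelling controls between the AM arrays thus stays open too.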
